A study of Mus musculus with 6 samples.

How the data were processed

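Poly(A) RNA from the cerebral cortex of C57BL/6 mice was sequenced directly, without conversion to cDNA, on a nanopore PromethION instrument, per the labels' protocols. The 6 samples were 3 wild type (WT) and 3 Fmr1 knockout (KO) samples, assigned from their titles. The labels do not say whether samples of a group came from separate animals. The spread between these samples, on which tests between samples rest, may thus be technical.

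The deposited table held 141196 transcripts of 52962 genes. Per the file headers, the authors gave the mean poly(A) tail length in nt of each transcript in each sample, the read count behind it, and an abundance in RPM. The tail estimator is not given in the sources used here. The submitters' processing notes name minimap2 2.17, SAMtools 1.9, Salmon 1.5.2, DESeq2 and the mouse build mm10, without their roles. The deposited table also holds the authors' own comparison, with a log2 fold change, its standard error, a test score and an unadjusted p-value per transcript. The header does not state the direction of its log2 values. They were taken as WT over KO because Fmr1, low in the knockout libraries, is positive there. Across 19904 transcripts they ran opposite to the KO over WT changes found here with edgeR (Pearson's r = -0.73). Multiplied by its read count, 100% of deposited mean tails from 3 or more reads came out whole within 0.01, so the values are means over whole-number tail lengths. Deposited RPM values were whole multiples of the value of 1 read, within the same tolerance, for 99.9% of values in WT replicate 1 and 100% in the other libraries, which allowed whole reads to be recovered.

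Reads with a tail numbered 3214196, 3621378 and 3849077 in WT replicates 1 to 3 and 3540416, 2404074 and 3443862 in the knockout replicates. Depth therefore limits transcripts with few reads, whose mean tail rests on a small sample. Transcript identifiers were matched to GENCODE mouse release 21 on the mm10 assembly (GRCm38), which held 97.9% of them. Coordinates and transcript classes were taken from it, and its release may not be the one the authors used.

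Tail lengths were compared as log2(mean nt + 1) with limma 3.58.1 (empirical Bayes, variance trend on mean tail length) for the 16168 transcripts with at least 10 tail reads in each of the 6 samples. These held 96.7% of all tail reads. Sample-wide tail length was the median over these transcripts, compared with a two-sided exact permutation test, for which 3 against 3 samples cannot give a p below 0.1. Abundance was tested per gene on the read counts behind the tails, summed over transcripts, with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test). All adjusted p-values used the Benjamini-Hochberg method with a threshold of 0.05. Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with the other genes, so its p-values rest on the spread between genes. The preset correlation treats genes as nearly independent, so its p-values can be very small with 6 samples. For tails, each gene was represented by the transcript with most reads. Values are given as mean ± SD over 3 samples unless stated otherwise, and log2 changes as KO over WT with their standard error.

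The 25 lists were set before the data were examined. They covered mRNAs reported as bound by FMRP, mRNAs reported as controlled by CPEB1, poly(A) enzymes and binding proteins, the Fmr1 family, ribosomal proteins, mitochondrially encoded RNAs, nuclear respiratory chain subunits, translation factors, glycolysis, synaptic vesicle, postsynaptic, immediate early, heat shock, histone, tubulin and actin, ubiquitin and proteasome, nuclear long non-coding RNA, and markers of inhibitory neurons, excitatory neurons, astrocytes, oligodendrocytes, microglia, vessels and meninges, blood and neighbouring brain regions. The FMRP and CPEB1 lists are subsets from general knowledge, drawn up from other samples.

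Named genes followed a rule set at the same time, and a few genes it names are not reported here. Fmr1 came first. Then came up to 8 increases and 8 decreases with the largest log2 change among genes past the threshold with all knockout samples on one side of all WT samples. Where fewer than 5 passed, the 10 with the smallest unadjusted p were named. Each list contributed up to 4 members past the threshold, or otherwise up to 2 with the most reads. In WT, the 5 longest and 5 shortest tails among the 2665 genes with the most reads were named.

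Both were tested on simulated data with 200 changed genes, 100 at each of 2 sizes. At a simulated fold of 1.19 in tail length, 18% of changed transcripts among 16168 were recovered, and at 1.41, 54%. For abundance, 12376 genes were run, and 63% of changed genes were recovered at a fold of 1.5 and 98% at a fold of 2. The changed genes for abundance were drawn only from those above a minimum mean read count, so these rates do not cover genes with few reads. Unchanged features gave 6 false calls for tails and 12 for abundance. Alternatives covered read minimum, level, scale, centring, weights, replicate number as a block, DESeq2 1.42.0, count filters, set tests and leaving out each sample. Alternatives added after the data had been seen were a variance trend on read number, reads recovered from RPM, limma on log2(RPM + 1) and an offset per library for transcript length. The length offset came from a lowess curve (span 0.3) of each library's deviation in log2 CPM on log2 transcript length. A median over reads could not be run, because only means were available. No pair of libraries within a group agreed within sampling noise: the chi-square per gene between pairs ranged from 1.26 to 2.16, where sampling noise alone gives about 1. R 4.3.3 and Python 3.11.15 were used.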

Results

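Direct RNA sequencing of mouse cortex gave a poly(A) tail length and an abundance for each transcript in 3 WT and 3 Fmr1 knockout samples. Fmr1 encodes FMRP, an RNA-binding protein that represses translation in neurons, and the series compares tail lengths with and without it. The libraries held between 2404074 and 3849077 reads with a tail estimate.

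Fmr1 (ENSMUSG00000000838, chromosome X, 68678541 to 68717963, mm10) was low in every knockout library. Its abundance was 41.7, 45.1 and 46.4 CPM in the WT libraries and 10.9, 11.8 and 8.22 CPM in the knockout libraries. The log2 change was -2.13 ± 0.15 (SE; edgeR, adjusted p = 1.22e-10), and the knockout level was 23.2% of WT. In the authors' deposited table, the log2 WT over KO of 5 of its protein-coding transcripts was 2.84, 2.86, 1.87, 2.63 and 1.98. The direction of those values was taken from Fmr1, so their sign is no separate evidence.

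In WT cortex, tail length differed widely between gene groups. The median over 10651 genes was 143 ± 2.66 nt (SD, n = 3). RNAs encoded by the mitochondrial genome had a median of 65.1 ± 0.35 nt and ribosomal protein mRNAs 83.7 ± 0.66 nt. Nuclear respiratory chain subunits had 108 ± 1.48 nt, nuclear long non-coding RNAs 211 ± 6.50 nt, and mRNAs reported as bound by FMRP 152 ± 2.30 nt. The differences between these groups exceeded the spread between libraries many times over.

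The shortest tails among 2665 well-covered genes were those of the globins Hbb-bt (42.5 ± 1.10 nt), Hbb-bs (50.5 ± 1.03 nt) and Hba-a2 (51.1 ± 1.51 nt) and of the mitochondrial tRNA genes mt-Tc (50.5 ± 1.86 nt) and mt-Ta (51.3 ± 2.23 nt). The longest belonged to the non-coding RNAs Snhg11 (335 ± 10.7 nt), Mir124a-1hg (305 ± 1.91 nt) and Meg3 (300.0 ± 4.09 nt), followed by Ogt (242 ± 11.97 nt), which encodes O-GlcNAc transferase, and Rsrp1 (220 ± 3.86 nt). In the knockout, Rsrp1 had 186 ± 10.3 nt, a difference that did not pass the limma test over all transcripts (adjusted p = 0.74).

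**Figure D1:**
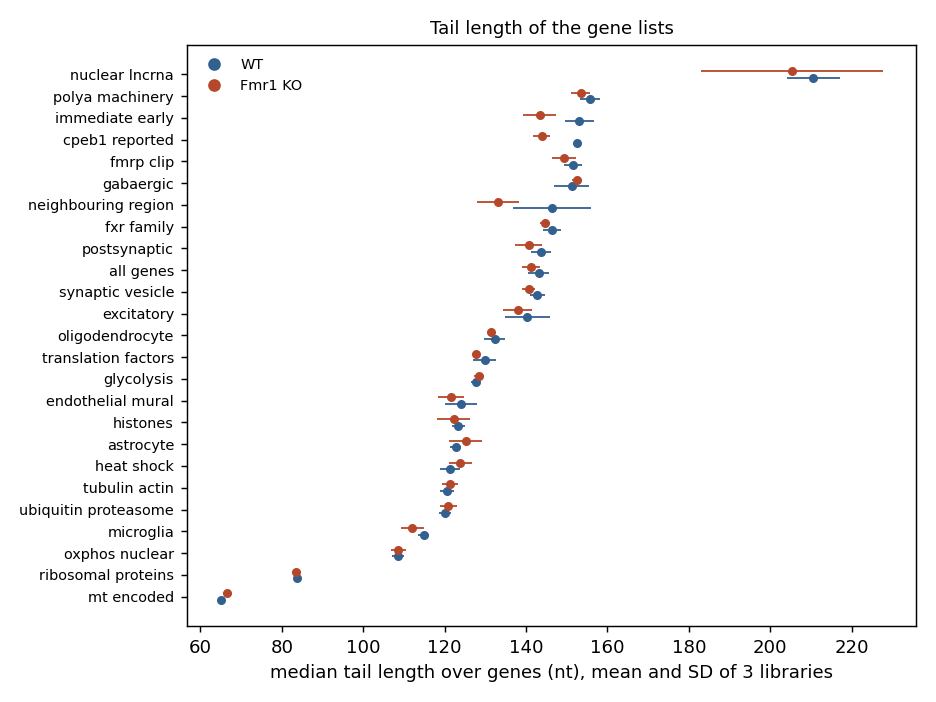
Median poly(A) tail length in nt (x axis) of each gene list (y axis) in WT and Fmr1 knockout cortex; points are the mean over 3 libraries and bars their SD. Mitochondrially encoded RNAs lie near 65 nt and nuclear long non-coding RNAs near 211 nt in WT.

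Across 11323 genes, longer tails went with lower abundance. Spearman's rho between tail length and RPM was -0.289 ± 0.00784 in WT (SD over 3 libraries) and -0.278 ± 0.00503 in the knockout. Longer transcripts had longer tails, with rho 0.504 on average in WT. Between the tail change and the abundance change from WT to knockout, rho was 0.0571. These correlations are across genes, which are not independent replicates.

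The whole distribution of tails was similar in both genotypes. The median tail was 143 ± 2.59 nt in WT and 142 ± 2.11 nt in the knockout (SD, n = 3 each), a difference of -1.93 nt (two-sided exact permutation p = 0.4, where the smallest possible is 0.1). Single libraries had medians of 140.6, 144 and 146 nt in WT and 141, 139.6 and 144 nt in the knockout. The share of reads that carried a tail estimate was 80.6 ± 4.40% in WT and 75.8 ± 1.36% in the knockout (exact permutation p = 0.2).

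**Figure D2:**
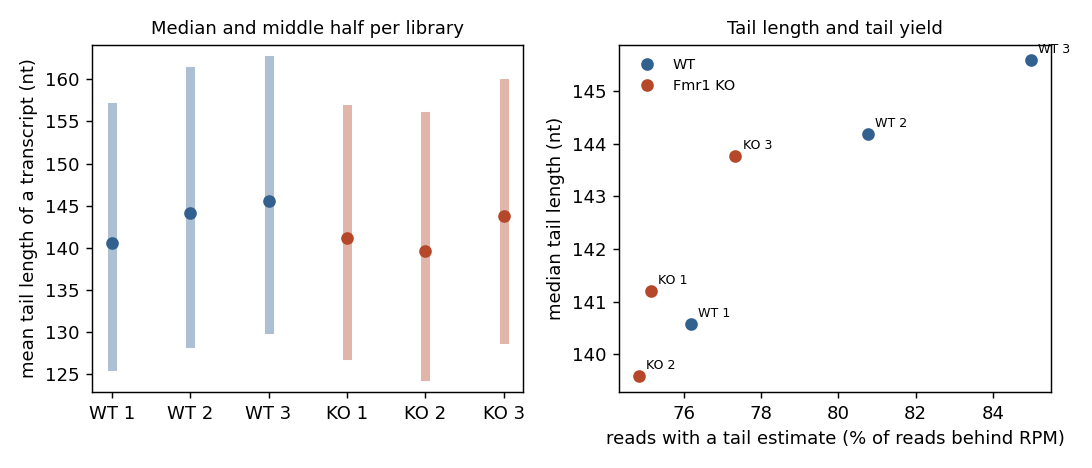
Left, median (point) and interquartile range (bar) of transcript tail lengths in nt per library; right, the median in nt against the percent of reads with a tail estimate. The medians run from 139.6 to 146 nt, and the genotypes overlap.

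No single transcript passed the test for tail length between knockout and WT: limma called 0 of 16168, with 944 at an unadjusted p under 0.05, of which 667 were shorter in the knockout and 277 longer. Tails of 1770 transcripts (10.9%) had the genotypes fully apart, where chance gives 10% over both directions. Of these, 1218 were shorter in the knockout and 552 longer. Over all 16168 transcripts, 58.8% had a log2 change below 0, so counts of shorter members in a list stand beside that share. The smallest p-values, none of which passed, belonged to transcripts of Snrpb2, a spliceosome protein (139 ± 5.93 nt in WT and 103 ± 3.63 nt in the knockout), Epn2 (163 ± 5.04 and 124 ± 2.79 nt), the gluconeogenic enzyme Pck2 (118 ± 4.64 and 150 ± 0.21 nt) and Stxbp2 (186 ± 13.8 and 123 ± 8.87 nt), each at adjusted p = 0.56. Next came Cox7a2 (119 ± 3.27 and 93.4 ± 5.76 nt), Mrpl52 (78.6 ± 4.69 and 98.7 ± 2.74 nt), Pcdh10 (136 ± 3.98 and 114 ± 1.36 nt), Eno1b (122 ± 5.70 and 94.5 ± 6.05 nt) and the carnitine transporter Slc22a5 (191 ± 8.36 and 148 ± 6.33 nt), at adjusted p = 0.70. All but Eno1b and Cox7a2 rested on at most 178 reads over the 6 samples, and reads of Eno1b can be shared with its copy Eno1. The transcripts of Snrpb2, Epn2, Pck2, Cox7a2, Mrpl52 and Pcdh10 were not the most covered of their genes. Their tails need not stand for those genes as a whole. With weights from read number 22 transcripts passed, 13 longer and 9 shorter in the knockout. Such weights take variance to fall as reads rise, which spread between libraries need not do. With a variance trend on read number, chosen after seeing the data, 11 passed, 2 longer and 9 shorter.

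Immediate early transcripts, which neurons make within minutes of activity, had shorter tails in the knockout as a group. The list median was 153 ± 3.48 nt in WT and 143 ± 4.08 nt in the knockout (exact permutation p = 0.1, the smallest possible). Of 25 members, 20 had a shorter mean and 5 a longer one, where 58.8% of all transcripts tested were shorter. The list was called by camera (median log2 -0.09, adjusted p = 0.000415). The median was -0.05 without WT replicate 3, and the call was lost with an estimated correlation (adjusted p = 0.95) and with fry (adjusted p = 0.50). No member passed over all transcripts, and 5 passed when adjusted over the list alone: Nr4a1 (172 ± 4.80 nt in WT, 142 ± 5.79 nt in the knockout), Egr4 (154 ± 2.87 and 132 ± 5.15 nt), Egr1 (160 ± 3.13 and 139 ± 4.37 nt), Fos (170 ± 4.77 and 145 ± 6.85 nt) and Junb (132 ± 5.64 and 115 ± 4.68 nt). These 5 were also among the 11 passing with the variance trend on read number. Npas4 (192 ± 9.46 and 192 ± 4.64 nt), Jun (138 ± 4.58 and 137 ± 5.30 nt) and Egr3 (154 ± 15.4 and 153 ± 4.87 nt) had like means in both genotypes, and were picked after their values were seen. The table holds 2 gene records named Jund, and both count in the list.

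**Figure D3:**
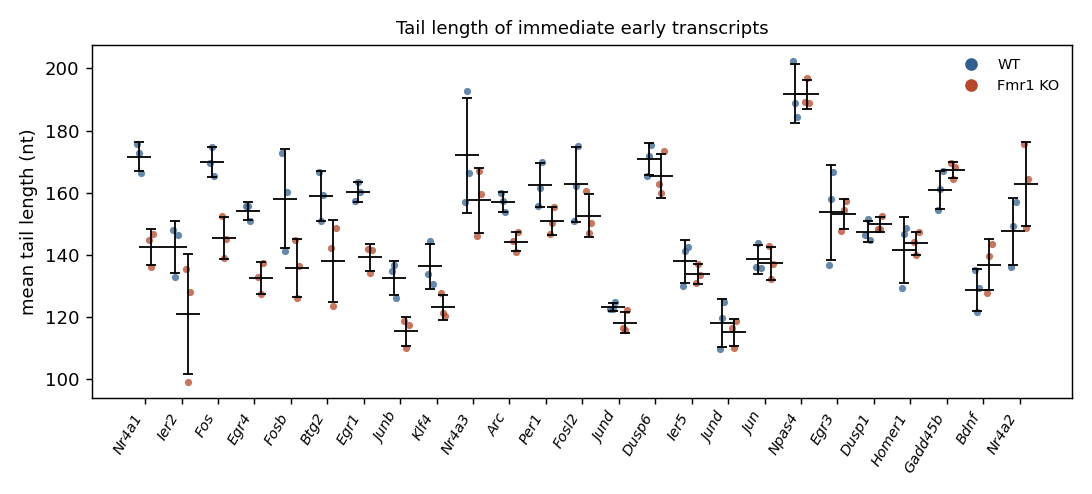
Mean poly(A) tail length in nt (y axis) of the 25 immediate early transcripts measured (x axis, ordered by log2 change); points are libraries and bars the mean and SD of 3. Tails of Nr4a1, Fos, Egr4, Egr1 and Junb are shorter in every knockout library than in any WT library.

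Heat shock transcripts and mitochondrially encoded RNAs had longer tails relative to other genes. Of 17 heat shock members 14 were longer in the knockout (median log2 0.06, camera adjusted p = 0.000415; adjusted p = 0.95 with an estimated correlation), with medians of 0.02 without WT replicate 1, 0.02 without knockout replicate 3 and 0.04 at 30 reads. Among them were the chaperone Hspa8 (107 ± 2.99 nt in WT and 114 ± 2.48 nt in the knockout) and Hsp90ab1 (123 ± 1.31 and 123 ± 1.20 nt). Of 27 mitochondrially encoded RNAs 24 were longer (median log2 0.03, and 0.05 when centred by the sample median; camera adjusted p = 8.70e-06; adjusted p = 0.95 with an estimated correlation). The difference was small: mt-Co1 had 75.4 ± 0.63 nt in WT and 76.9 ± 0.74 nt in the knockout, and mt-Co2 had 64.9 ± 0.32 and 66.3 ± 0.54 nt. No member of either list passed over all transcripts or adjusted over the list alone. Hspa8 passed with the variance trend on read number (limma, adjusted p = 0.0231). With weights from read number 8 mitochondrially encoded RNAs passed, among them mt-Co1 (adjusted p = 3.94e-05) and mt-Co2 (adjusted p = 4.37e-06), as did Hspa8 (adjusted p = 0.000309). These weights take variance to fall as reads rise, which spread between libraries need not do, so the weighted calls are weak evidence. Without weights, limma gave unadjusted p = 0.372 for mt-Co1 and 0.296 for mt-Co2.

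The FMRP and CPEB1 lists were not called for tail length. Their counts of shorter members stand beside 58.8% shorter over all transcripts tested. Of 150 mRNAs reported as bound by FMRP, 107 were shorter and 43 longer (median log2 -0.02, camera adjusted p = 0.55), with Snap25 at 158 ± 0.95 nt in WT and 155 ± 1.64 nt in the knockout and Cpe at 140.5 ± 0.93 and 139 ± 0.82 nt. Of 23 mRNAs reported as controlled by CPEB1, 16 were shorter (median log2 -0.04, camera adjusted p = 0.33), and the list median was 153 ± 0.0646 nt in WT and 144 ± 2.02 nt in the knockout, a difference of -8.73 nt (exact permutation p = 0.1, the smallest possible). Camk2a was at 138 ± 5.34 and 139 ± 3.78 nt and Ndufv2 at 112 ± 1.65 and 109 ± 2.995 nt. No member of these lists passed adjusted over the list alone.

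The other 19 lists tested for tails were not called by camera. An even split of members in them differs from all transcripts tested, of which 58.8% were shorter. In them 1 member passed adjusted over the list alone, the oligodendrocyte enzyme gene Aspa (152 ± 2.60 nt in WT and 131 ± 2.26 nt in the knockout, 317 reads). Ribosomal protein mRNAs had 41 shorter and 42 longer members (adjusted p = 0.37), with Rps29 at 73.5 ± 0.65 nt in WT and 73.0 ± 0.51 nt in the knockout. Nuclear respiratory chain subunits (adjusted p = 0.73) had Cox8a at 121 ± 2.81 and 122 ± 0.45 nt, translation factors (adjusted p = 0.81) had Eef1a1 at 104 ± 0.66 and 104 ± 1.45 nt, and glycolytic enzymes (adjusted p = 0.72) had Gapdh at 113 ± 2.06 and 112 ± 0.63 nt. Poly(A) enzymes and binding proteins (adjusted p = 0.45) had Pabpc1 at 114 ± 4.16 and 113 ± 3.41 nt, and the Fmr1 family (adjusted p = 0.89) had Cyfip2 at 138 ± 1.75 and 142 ± 3.54 nt. Synaptic vesicle genes (adjusted p = 0.89) included Atp6v0c at 125 ± 0.58 and 124 ± 0.81 nt, and postsynaptic genes (adjusted p = 0.55) included Ppp3ca at 135 ± 1.94 and 135 ± 3.24 nt. Tubulins and actins (adjusted p = 0.45), ubiquitin and proteasome genes (adjusted p = 0.45), nuclear long non-coding RNAs (adjusted p = 0.81) and histones (adjusted p = 0.37) were not called either, with Tuba1a at 107 ± 0.79 and 107 ± 1.25 nt and Ubb at 119 ± 1.12 and 119 ± 1.43 nt. Among cell type markers, the adjusted p was 0.45 for inhibitory neurons, 0.73 for excitatory neurons, 0.81 for astrocytes, 0.45 for oligodendrocytes, 0.89 for microglia, 0.58 for vessels and meninges and 0.89 for neighbouring regions. Sst had 146 ± 1.25 nt in WT and 150.3 ± 0.77 nt in the knockout, Nrgn 122 ± 1.95 and 121 ± 1.60 nt, Cst3 99.0 ± 0.78 and 96.6 ± 0.80 nt, Mbp 122 ± 0.89 and 121 ± 2.32 nt and C1qb 110.1 ± 1.78 and 109.7 ± 2.31 nt. The list of neighbouring regions had a median of 146 ± 9.51 nt in WT and 133 ± 5.18 nt in the knockout, a difference of -13.4 nt (exact permutation p = 0.1, the smallest possible), but 6 of its 13 members were shorter and 7 longer, with a median log2 change of 0.00. The blood list had fewer than 5 measured members and was not tested for tails.

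RNA abundance differed between the genotypes for 129 of 12543 genes tested, with 72 higher and 57 lower in the knockout (edgeR, adjusted p under the threshold of 0.05), and 79 of them changed by less than 1.5-fold. Fmr1 fell as given above. Eno1b (chromosome 18, 48045335 to 48048412), a close copy of the glycolytic enzyme gene Eno1, fell from 353 ± 16.1 to 53.0 ± 3.199 CPM (log2 -2.73 ± 0.08, adjusted p = 1.02e-19), while Eno1 (chromosome 4, 150236721 to 150248879) rose from 527 ± 18.5 to 936 ± 36.1 CPM (log2 0.83 ± 0.05, adjusted p = 4.77e-11). Reads can be split between such copies, so each value alone is uncertain.

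The largest increases came from 1 stretch of chromosome 14. Tmem254a (25923300 to 25927672) rose from 13.4 ± 1.88 to 52.1 ± 5.07 CPM (log2 1.93 ± 0.13, adjusted p = 1.22e-10), Tmem254b from 10.7 ± 0.61 to 26.5 ± 2.09 CPM and Tmem254c from 2.58 ± 0.22 to 6.59 ± 1.69 CPM. The neighbouring Plac9a rose by log2 1.51 ± 0.34 and Plac9b by 1.47 ± 0.34. These genes are near-identical copies, and their separate values are uncertain. The nuclear import factor Kpna2 also rose (log2 1.04 ± 0.24). Several calls were lost on leaving out single libraries or with another method. Kpna2 was lost without WT replicate 2 (adjusted p = 0.195) and without knockout replicates 1 (0.0573), 2 (0.133) and 3 (0.148), with limma on log2(RPM + 1) (0.227) and on reads recovered from RPM (0.0662). Plac9a was lost without WT replicates 1 (0.0676) and 3 (0.0508) and knockout replicates 1 (0.0676), 2 (0.102) and 3 (0.125) and with limma on log2(RPM + 1) (0.0951), and Plac9b without WT replicate 2 (0.172) and knockout replicates 1 (0.130) and 2 (0.171). Tmem254c was lost without WT replicates 1 (0.0634), 2 (0.173) and 3 (0.0775) and knockout replicates 2 (0.219) and 3 (0.194). The replicate number as a block lost Kpna2 (adjusted p = 0.0583), Plac9b (0.0583) and Tmem254c (0.0603), and an offset for transcript length lost Plac9b (0.0502) and Tmem254c (0.0727).

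Ttr (chromosome 18, 20665280 to 20674321), the thyroid hormone carrier made in choroid plexus, had the largest decrease, log2 -4.69 ± 0.64 (adjusted p = 6.45e-05). Its WT libraries held 422, 28.4 and 821 CPM and its knockout libraries 17.98, 22.8 and 10.3 CPM, so that WT replicate 2 lay near the knockout. Its log2 change was -5.24 without WT replicate 2 and -3.75 without WT replicate 3, and limma on log2(RPM + 1) did not call it (adjusted p = 0.145). Serpina3n, an acute-phase protease inhibitor, fell by log2 2.07 on average, with 63.4 CPM in WT replicate 2 against 11.96 and 12.1 CPM in the other WT libraries, and without that library its log2 change was -0.78 and did not pass (adjusted p = 0.19). Cdhr1 (log2 -1.79 ± 0.28), Proser2 (log2 -1.87 ± 0.36), Gm35021 (log2 -2.56 ± 0.45) and the pseudogene Gm10499 (log2 -3.35 ± 0.62) also fell, the last from 12, 20 and 20 reads in WT to 0, 4 and 0 in the knockout. Serpina3n was also lost without knockout replicates 1 (adjusted p = 0.130), 2 (0.114) and 3 (0.1004). Proser2 was lost without knockout replicates 1 (0.0720) and 3 (0.0663), and Gm10499 without the same libraries (0.0534 and 0.0509). Without knockout replicate 1 the log2 change of Gm35021 was -3.57, and limma on log2(RPM + 1) did not call Serpina3n (adjusted p = 0.205), Cdhr1 (0.0799), Proser2 (0.0566) or Gm10499 (log2 -0.18, adjusted p = 0.743). Without knockout replicate 2 the other knockout libraries held 0 reads of Gm10499, and its fitted log2 change was -7.09.

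**Figure D4:**
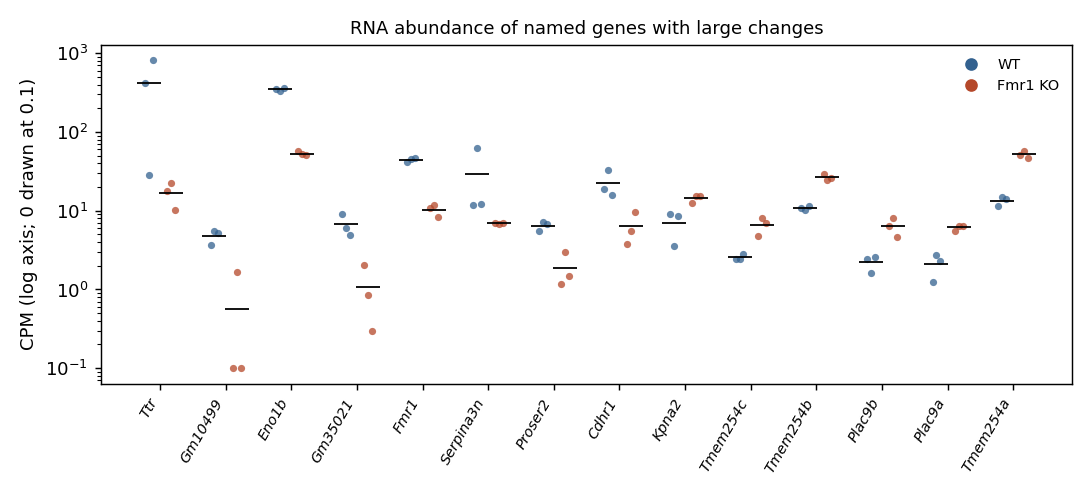
Abundance in CPM (y axis, log scale, values of 0 drawn at 0.1) of 14 genes with large changes (x axis); points are libraries and lines the mean of 3. Ttr spans 28.4 to 821 CPM among WT libraries, and Tmem254a is at 13.4 CPM in WT and 52.1 CPM in the knockout on average.

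The count of changed genes depended on single libraries. It was 206 without WT replicate 1, 72 without WT replicate 2, 148 without WT replicate 3, 72 without knockout replicate 1, 57 without knockout replicate 2 and 59 without knockout replicate 3. DESeq2 called 58 genes, 55 of them among the 129. Of Fmr1 and the genes named for the largest changes, only Eno1b and Ttr were given an adjusted p by DESeq2. The others, Fmr1 included, had a p-value but no adjusted p, so their absence from the 58 is not a failed test.

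Among lists, ribosomal protein mRNAs were higher in the knockout. All 83 measured members had a higher mean, 6 passed over all genes and 62 passed adjusted over the list alone (median log2 0.17, camera adjusted p = 1.69e-30; adjusted p = 0.20 with an estimated correlation). Rpl13a rose from 716 ± 71.2 to 906 ± 33.8 CPM, Rpl34 by log2 0.29 ± 0.06, Rpl9 by 0.26 ± 0.06 and Rpl12 by 0.25 ± 0.06. Of 85 nuclear respiratory chain subunits 78 were higher, 6 passed and 16 passed adjusted over the list alone (median log2 0.09, camera adjusted p = 1.79e-11; adjusted p = 0.20 with an estimated correlation), with Ndufb9 (log2 0.28 ± 0.06), Cox4i1 (0.25 ± 0.06), Cox6c (0.23 ± 0.05) and Ndufb7 (0.32 ± 0.07). With an offset for transcript length, added after seeing the data, the median log2 was 0.03 for these subunits (adjusted p = 0.0136) and 0.09 for ribosomal proteins (adjusted p = 4.05e-12). Of 29 mitochondrially encoded RNAs 22 were higher and 4 passed (7 adjusted over the list alone; camera adjusted p = 5.58e-06; adjusted p = 0.25 with an estimated correlation). The median log2 of this list was 0.11, 0.04 without knockout replicate 1, 0.03 on reads recovered from RPM (adjusted p = 0.000779), and -0.02 with the length offset, which ended the call (adjusted p = 0.548). The ribosomal RNA mt-Rnr2 rose from 18549 ± 1068 to 26287 ± 1722 CPM, mt-Rnr1 by log2 0.49 ± 0.05, mt-Ta by 0.40 ± 0.09 and mt-Tn by 0.34 ± 0.09.

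Short transcripts were higher and long transcripts lower in the knockout. The median log2 change was 0.07 in the eighth of genes with the shortest transcripts (median 977 nt) and -0.07 in the eighth with the longest (median 7397 nt), and rho with length was -0.198 across genes, which are not independent replicates. Slopes per doubling of length were taken on each library's deviation in log2 CPM from the gene's mean over libraries. They were 0.0353, 0.0310 and -0.00382 in WT and -0.0269, -0.0198 and -0.0158 in the knockout (exact permutation p = 0.1, the smallest possible). This centring makes the group means mirror each other, so only their difference has meaning. The ribosomal protein list had a median transcript length of 831 nt and the FMRP list one of 6644 nt.

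The mRNAs reported as bound by FMRP were lower. Of 152 members 95 were lower and 57 higher, 5 fell and 0 rose past the threshold, and 6 passed adjusted over the list alone (median log2 -0.03, camera adjusted p = 0.00518; adjusted p = 0.20 with an estimated correlation). With an offset for transcript length, added after seeing the data, the list was no longer called (median log2 0.02, adjusted p = 0.83). Clasp2, a microtubule plus-end protein, fell from 126 ± 11.6 to 43.0 ± 5.62 CPM (log2 -1.53 ± 0.10, adjusted p = 2.11e-11). Map1a, which stabilises microtubules, fell by 0.34 ± 0.06 on the log2 scale (346 ± 20.7 to 273 ± 3.82 CPM), Dlg2, a postsynaptic scaffold, from 98.1 ± 4.71 to 73.7 ± 4.22 CPM, and Prrc2a from 145 ± 2.04 to 111 ± 14.7 CPM. The Fmr1 family list was called lower (adjusted p = 0.0275; adjusted p = 0.20 with an estimated correlation), although its median log2 was 0.05 and its mean -0.20: the only member of 8 past the threshold, over all genes or adjusted over the list alone, was Fmr1. This call was lost without WT replicate 1 (adjusted p = 0.0745) and knockout replicate 3 (0.0566), and with the length offset (0.0866), and the median log2 was 0.11 without WT replicate 1, 0.03 without WT replicate 2, 0.00 without WT replicate 3 and 0.08 with the offset.

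Immediate early genes moved both ways. Of 29 members, 4 fell, 2 rose and 11 passed adjusted over the list alone, 7 of them lower (median log2 -0.19, camera adjusted p = 0.0324; adjusted p = 0.68 with an estimated correlation). The list call was lost without WT replicate 2 (adjusted p = 0.12, median -0.06), WT replicate 3 (0.76, median 0.00), knockout replicate 1 (0.48, median -0.09) and knockout replicate 2 (0.062), and the median was -0.35 without WT replicate 1 and -0.10 without knockout replicate 3. On reads recovered from RPM it was -0.05 (adjusted p = 0.0293). Btg2, which promotes deadenylation and also belongs to the CPEB1 and poly(A) enzyme lists, fell from 33.1 ± 4.12 to 14.2 ± 0.96 CPM (log2 -1.22 ± 0.15, adjusted p = 1.24e-05). Jun fell by log2 0.64 ± 0.11 (45.6 ± 2.67 to 29.1 ± 2.49 CPM), Ccn1 from 15.7 ± 6.14 to 5.58 ± 1.95 CPM and Npas4 from 24.3 ± 7.07 to 12.4 ± 2.49 CPM. Homer1 (log2 0.35 ± 0.08) and Ier5 (0.48 ± 0.10) rose.

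Nuclear long non-coding RNAs were lower, with 10 of 12 below WT, 2 past the threshold and 4 adjusted over the list alone (median log2 -0.26, and -0.48 without knockout replicate 3; camera adjusted p = 7.27e-06; adjusted p = 0.20 with an estimated correlation). Snhg11 fell from 182 ± 18.5 to 117 ± 17.01 CPM and Meg3 from 173 ± 12.6 to 121 ± 21.1 CPM. Heat shock genes were higher in 13 of 17 cases, with 2 past the threshold and 6 adjusted over the list alone (median log2 0.15, camera adjusted p = 1.88e-05; adjusted p = 0.20 with an estimated correlation), namely Dnajb1 (54.9 ± 5.01 to 78.3 ± 0.69 CPM) and the stress transcription factor Atf4 (77.4 ± 7.66 to 102 ± 9.82 CPM). Translation factors (51 of 64 higher, 0 past the threshold and 0 adjusted over the list alone, camera adjusted p = 0.000583) and ubiquitin and proteasome genes (35 of 43 higher, 7 adjusted over the list alone, camera adjusted p = 8.53e-06) were also called higher, each at adjusted p = 0.20 with an estimated correlation. With the length offset the ubiquitin and proteasome median went from 0.11 to 0.07 (adjusted p = 0.00643). Psmd14 rose by log2 0.32 ± 0.07, while Eef1a1 was at 2125 ± 110 and 2222 ± 67.8 CPM. Tubulins and actins were called higher (19 of 28, adjusted p = 0.0324; adjusted p = 0.30 with an estimated correlation), with Stmn1 higher (log2 0.22 ± 0.05) and Map1a lower and 2 members past the threshold adjusted over the list alone. The call of tubulins and actins was lost without WT replicate 2 (adjusted p = 0.130) and knockout replicates 2 (0.0643) and 3 (0.0566), and with the length offset (0.137) and on reads recovered from RPM (0.132).

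**Figure D5:**
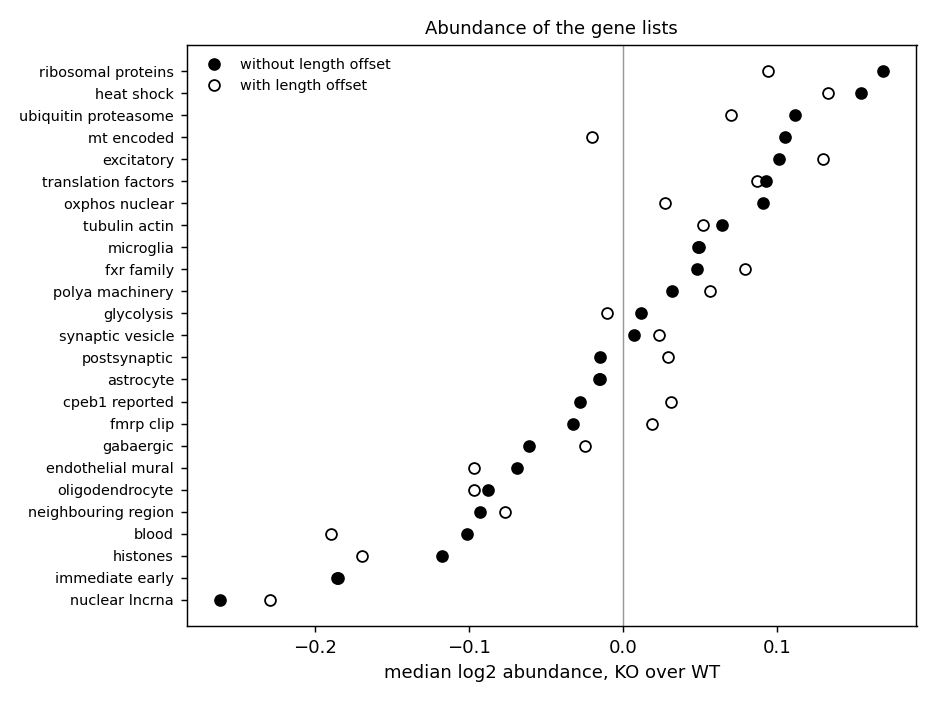
Median log2 abundance change, KO over WT (x axis), of the members of each list (y axis), without (filled) and with (open) an offset per library for transcript length. The median of ribosomal proteins is 0.17 without the offset and 0.09 with it.

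Cell type markers gave small median differences. Excitatory neuron markers were called higher (10 of 16, median log2 0.10, adjusted p = 0.0314; adjusted p = 0.26 with an estimated correlation), with Nrgn rising from 2498 ± 141 to 2874 ± 121 CPM. Oligodendrocyte markers were called lower (17 of 21, median log2 -0.09, adjusted p = 0.0324; adjusted p = 0.43 with an estimated correlation), although Mbp was at 1994 ± 205 and 2021 ± 100.4 CPM. Adjusted over the list alone, 4 excitatory and 1 oligodendrocyte markers passed. The excitatory call was lost without WT replicate 1 (adjusted p = 0.217) and knockout replicates 2 (0.0645) and 3 (0.0688), and the oligodendrocyte call without WT replicate 1 (0.283) and knockout replicate 3 (0.165). The excitatory median log2 was 0.03 without WT replicate 1, 0.15 without WT replicate 2, 0.16 without knockout replicate 1, 0.05 without knockout replicate 3 and 0.07 on reads recovered from RPM. The oligodendrocyte median was -0.05 without WT replicate 1. The lists for inhibitory neurons (adjusted p = 0.50), astrocytes (0.59), microglia (0.28), vessels and meninges (0.0799), blood (0.53) and neighbouring regions (0.0514) were not called, and 3, 2, 0, 1, 0 and 2 of their members passed adjusted over the list alone. For inhibitory neurons the median log2 was -0.06 and the mean 0.02, and for astrocytes -0.02 and 0.01. For neighbouring regions the median was -0.09 and the mean -0.52, with 5 members higher and 13 lower. Single members did change: Sst rose from 548 ± 35.2 to 652 ± 34.5 CPM, Apoe from 1117 ± 98.7 to 1374 ± 84.2 CPM, and Igf2 fell from 30.6 ± 1.89 to 18.9 ± 1.29 CPM. C1qb was at 93.9 ± 8.32 and 94.5 ± 3.16 CPM and Hbb-bs at 506 ± 143 and 488 ± 41.8 CPM.

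The remaining lists were not called for abundance. The CPEB1 list (adjusted p = 0.0514) had 2 members past the threshold, Btg2 and Jun, both lower. Glycolysis (adjusted p = 0.0514) had Eno1, poly(A) enzymes (median log2 0.03, mean -0.03, adjusted p = 0.9998) had Btg2, and histones (adjusted p = 0.43) had Hist1h1c, which fell from 37.8 ± 2.48 to 24.6 ± 4.36 CPM. Postsynaptic genes (adjusted p = 0.72) had 3 rising, among them Cacng3 (log2 0.32 ± 0.07), and Dlg2 falling. Synaptic vesicle genes (adjusted p = 0.61) had 0 past the threshold, with Snap25 at 2398 ± 96.8 and 2434 ± 48.3 CPM. Adjusted over the list alone, the CPEB1 list had 2 members past the threshold, glycolysis 1, poly(A) enzymes 2, histones 1, postsynaptic genes 6 and synaptic vesicle genes 4.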

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

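Of the tests here, those on the relative tail shift and on summed copies, the variance trend on read number and the length offset itself were chosen after the data had been seen. What the length offset would show for the 4 lists weighed here, and the tests on the tail and abundance changes of immediate early genes, on other genes of the chromosome 14 stretch and on splits of the samples, were written down before their results were seen.

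The Fmr1 transcripts left in the knockout had long tails, in reads too few for the tail comparison. The most covered transcript had a mean tail of 243 ± 35.8 nt in the knockout, from 3, 5 and 7 reads, against 178 ± 13.6 nt in WT, from 32, 46 and 53 reads (exact permutation p = 0.1, the smallest possible with 3 against 3). Pooled over the transcripts of the gene, the means were 225 ± 21.7 and 176 ± 12.5 nt, and the gene-level limma test gave adjusted p = 0.70, or 0.0208 with a variance trend on read number.

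Shorter tails of immediate early transcripts in the knockout were weighed against a shift of all tails. Relative to the median tail of each library, the list still differed by a log2 of -0.0764, with a pooled SD of 0.0214. Every knockout library lay below every WT library (exact permutation p = 0.1, the smallest possible). The list thus fell by more than the library median. The CPEB1 list (-0.0665) was apart in the same way. So was the neighbouring region list (-0.119), though 6 of its 13 members were shorter and 7 longer. Apart in the other direction were mitochondrially encoded RNAs (0.0491), heat shock genes (0.0472), inhibitory neuron markers (0.0310) and ubiquitin and proteasome genes (0.0295). Such separation therefore cannot decide against a shift of all tails as the whole source. A shift in transcription before collection may shorten tails as a cohort ages, and would tie the tail change to the abundance change: over 27 genes of the list rho was 0.186 (permutation p = 0.352), which leaves this open. Genotype, untested apart from these, is also open. The share of reads with a tail estimate, which followed median tail length across libraries, averaged 75.8% in the knockout and 80.6% in WT. Its part in the list's difference was not tested apart from genotype. The number of lists called for tails was 3 in the real split and at most 1 in the other 9 splits of the 6 samples; 1 of 10 splits reached 3, and 10 splits are too few for a share under 0.05.

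Higher short and lower long transcripts in the knockout could come from length-dependent recovery of RNA, such as a difference in RNA integrity. With an offset for length, the FMRP list moved from a median log2 of -0.03 to 0.0186 and was not called (adjusted p = 0.831), so that its lower abundance may be part of the length trend. Ribosomal protein mRNAs kept a median of 0.0944 of their 0.17 (camera adjusted p = 4.05e-12) and nuclear long non-coding RNAs -0.229 of -0.26 (camera adjusted p = 0.000171). Both met the mark set beforehand for a source besides length. Those p-values took the preset inter-gene correlation of 0.01, where the estimates without the offset were 0.486 and 0.115. With an estimated correlation each list had adjusted p = 0.307, so length as the whole source stays open. Respiratory chain subunits went from 0.09 to 0.0274 with adjusted p = 0.0136, also 0.307 with an estimated correlation, which leaves them open, and an effect of genotype that follows length is open too. The real split called 129 genes and 13 lists, and the other 9 splits at most 1 gene and 8 lists. Those 9 splits called 7, 6, 6, 0, 0, 2, 8, 6 and 5 lists. Camera at the preset correlation thus often called lists in groups that mix the genotypes, and a single list call says little about genotype. For genes and for lists 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

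Eno1b and the Tmem254 genes were weighed against reads shared between near-identical copies. The summed reads of Eno1 and Eno1b changed by log2 0.166 ± 0.0522 (SE), far smaller in size than the -2.73 of Eno1b but above 2 standard errors, so that a different division of reads within the pair, for instance through a sequence variant, could account for most of the change and stays open. The summed reads of Tmem254a, Tmem254b and Tmem254c rose by log2 1.66 ± 0.0997 (SE). Each copy had already been seen to rise, so the sum had to rise and is no separate test. A division of reads among these copies alone could not raise all of them. Copy number of the chromosome 14 stretch (25887506 to 26207041) may differ between the mice, but 0 other tested genes lie inside it, so this stays open. Outside it, Anxa11 (log2 0.18 ± 0.12) and Slmap (0.13 ± 0.10) did not pass.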

How the results depend on the processing

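The variance trend on read number, the reads recovered from RPM, limma on log2(RPM + 1) and the length offset were chosen after seeing the data. The cause of the changes below was not tested, except that leaving out a sample removes data and that other filters change the genes tested. For tail length, 0 transcripts were called in 13 of 16 alternatives, leaving out each sample included (range 0 to 0), while 22 passed with weights from read number, 11 with a variance trend on read number and 15 at gene level with that trend. As 10 of 10 splits gave at least 0 calls and the highest other was 0, the splits say nothing here. The sample-wide difference kept its sign in all 11 alternatives and, leaving out each sample, ranged from -3.37 to -0.86 nt.

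Lists called for tails numbered 3 to 4 in 14 of 16 alternatives, and 0 with fry and 0 with an estimated correlation; leaving out each sample gave 3 to 4. For abundance, 13 lists became 0 with fry and 0 with an estimated correlation, 9 with the length offset (6 higher, 3 lower), and 11 to 14 leaving out each sample. With that offset the median of the FMRP list turned from -0.03 to 0.0186 and that of mitochondrially encoded RNAs from 0.11 to -0.0203, neither called, and the calls of the Fmr1 family and of tubulins and actins were lost. Genes called for abundance were 129 (72 higher, 57 lower), against 58 with DESeq2, 249 without a count filter, 40 with limma on log2(RPM + 1) (16 higher, 24 lower), 84 with the length offset (41 higher, 43 lower) and 101 on recovered reads (49 higher, 52 lower), and 57 to 206 leaving out each sample.

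The replicate number as a block called 0 tails, 92 genes (89 of them among the 129), 3 tail lists and 13 abundance lists, gave a paired difference of -1.93 nt (exact permutation p = 0.5) and a rho of 0.0554 between changes. The numbers did not pair the samples: correlations of deviations between equal numbers were 0.02, 0.00 and 0.01 for tails and 0.03, -0.07 and 0.05 for abundance, and not every sample correlated best with its own number. Spearman's rho of the changes ranged from 0.0337 to 0.0717 leaving out each sample, and that of WT tail length with abundance was -0.265 at 5 reads, -0.310 at 30 reads and -0.241 over transcripts, and -0.292 to -0.283 leaving out each sample. Named abundances kept their call in 143 of 186 cases that had an adjusted p. Genes to which DESeq2 or a count filter gave none are not among these cases. Named tails, none of them called, stayed uncalled in 130 of 131, and Eno1b passed with the variance trend on read number. The median over reads was not run. Depth limits tails: 9609 of 16168 transcripts had 30 reads in each sample.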

Other observations

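The tests of this part were chosen after the values had been seen. Among genes of the circadian clock, picked after their values were seen, 3 passed the test. Per2 rose from 9.70 ± 2.31 to 19.02 ± 1.91 CPM (log2 0.96 ± 0.19, edgeR adjusted p = 0.00724), Dbp from 70.5 ± 12.99 to 95.7 ± 9.10 CPM (adjusted p = 0.0271) and Bhlhe40 from 82.8 ± 13.3 to 110.5 ± 9.36 CPM (adjusted p = 0.0271). Arntl was at 27.4 ± 3.44 and 20.4 ± 2.34 CPM (adjusted p = 0.21) and Npas2 at 25.98 ± 3.91 and 19.6 ± 3.21 CPM (adjusted p = 0.26). Others that did not pass were Ciart (log2 0.62 ± 0.17), Per1 (0.25 ± 0.11), Per3 (0.26 ± 0.30), Tef (0.17 ± 0.07), Hlf (0.18 ± 0.08), Nr1d1 (0.01 ± 0.09), Nr1d2 (0.16 ± 0.09) and Clock (-0.13 ± 0.13). A candidate explanation is that the mice were collected at different times of day. The mean log2 change of Per1, Per2, Per3, Dbp, Tef, Hlf, Ciart, Nr1d1 and Nr1d2 minus that of Arntl, Clock and Npas2 was 0.644, against at most 0.382 in size in the other 9 splits of the 6 samples. The genes compared were chosen after some of their changes had been seen, so the gap is no independent evidence. With 10 splits no share under 0.05 can be reached, and an effect of genotype cannot be told apart from time of collection.

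Rbm3, a cold-induced RNA-binding protein, rose from 115 ± 9.35 to 163 ± 11.96 CPM (log2 0.51 ± 0.08, adjusted p = 0.000456), while its relative Cirbp was at 52.0 ± 6.91 and 48.1 ± 10.6 CPM. Hprt rose by log2 0.79 ± 0.13 with unlike knockout libraries: 466, 230 and 414 CPM, against 216, 224 and 209 CPM in WT. Each was singled out after its values were seen.

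Median tail length followed the share of reads with a tail estimate across the 6 libraries. Pearson's r was 0.90 (exact permutation p = 0.00417, adjusted 0.00833 over 2 relations) and Spearman's rho 0.94 (exact permutation p = 0.0167, adjusted 0.0167). Without WT replicates 2 and 3, the farthest from the median share, r was 0.86. With the number of tail reads, r was 0.82 (exact permutation p = 0.0194, adjusted 0.0194) and rho 0.94 (p = 0.0167, adjusted 0.0167), and r was 0.65 without WT replicate 3 and knockout replicate 2.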
